A study of Homo sapiens with 12 samples.

How the data were processed

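The series compares RNA of drug-treated and untreated H460 cells on 12 two-channel arrays. Drugs, doses, time (24 h), replicate numbers and channel orientation were read per the labels. The values deposited by the authors, taken here as log2, are log ratios of the channels per probe after a normalization and spot filter that are not given in the sources used here. The log base is not stated; a natural logarithm is not excluded, and it would change every size, the counts at a minimum absolute ratio of 1 and the choice of untested genes over 1.5, but no direction and no call by adjusted p. Spot intensities were not analysed here, so signal over background is unknown and the missing values stand in for it. Nor is the numerator of the ratio stated. A rule fixed before the data were examined set it: the sign common to all arrays for which CDKN1A, MDM2 and the median of the p53 list are positive in 5-FU.

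The table holds 8170 probes, of which 5930 match 1 gene, 79 several and 2161 none in the annotation; 5499 genes are represented, 407 of them by more than 1 probe. Probes of a gene were averaged within an array, and probes without a gene name were kept as features of their own and are not named, which gives 7739 features. The 5-FU arrays hold 4357 to 6411 values (21.5 to 46.7% missing) and the other arrays 6989 to 7644 (6.44 to 14.5% missing). Since 3595 probes (44.0%) have a value on every array, genes with missing values were kept wherever the comparison could be estimated, as the rule fixed in advance required. Array medians as deposited lie between 0.00162 and 0.0252, and each array was centred on its median.

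Forward and reversed 5-FU arrays were split into a drug ratio (the mean of the turned values) and a channel effect. The fit has 10 replicates, 2 per drug, and 1 observation for the channel effect, weighted 4 when 2 pairs of 5-FU arrays and 2 when 1 pair gave it. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The ratio is tested against 0, so the spread of untreated cultures is not a separate term. For the 4 drugs hybridised in 1 orientation the channel effect comes from the 5-FU arrays alone. That observation is fitted exactly, so its error is assumed from the replicate spread and its weight. The differences between the 2 pairs of 5-FU arrays gave it a mean variance of 0.0097, which the fit did not use. Standard errors for these 4 drugs may therefore be too small, and their calls too many. Comparisons were each drug against untreated RNA, 5-FU against cytarabine, paclitaxel against cytochalasin D, and the mean of the 3 DNA-directed drugs against the mean of the 2 cytoskeletal drugs. The other pairs of drugs, and the list tests on pairs, were chosen after seeing the data.

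The 23 gene lists were fixed in advance. They were tested against the other genes with limma's camera on pre-ranked moderated t (preset correlation 0.01), a departure from the planned camera on values, since that one takes no missing values; p values were adjusted over 115 tests for the drugs. The planned camera with an estimated correlation and fry were run on the 3536 genes without missing fitted values. "Adjusted over the list alone" means that p values were adjusted over the list's members only.

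Genes are named by a rule fixed in advance: per drug up to 10 of the largest rises and falls that pass and have the same sign in each replicate, up to 4 members per list with the largest change, MDM2, CDKN1A, GDF15, TYMS, CCNB1, ACTB and TUBB where measured, and per comparison of drugs the 5 largest each way. CDKN1A and TYMS lacked the values the fit needs, GDF15 had none, and CCNB1 is not on the array. Genes outside the rule are said to be chosen after their values were seen.

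The fit was tested on simulated data with 200 changed genes. For 5-FU it recovered 58 of 67 changes of 0.5, 64 of 67 of 1 and 66 of 66 of 2, with 10 false calls among 198. For cytarabine it recovered 47 of 67, 61 of 67 and 65 of 66. For paclitaxel against cytochalasin D it recovered 46 of 67, 60 of 67 and 66 of 66. Simulated values cannot show whether the error assumed for the channel effect holds on the real arrays. The share of false calls against untreated RNA for cytarabine, cisplatin, paclitaxel and cytochalasin D therefore stays unknown. Alternatives tried were no channel term (which also keeps 5-FU replicates with 1 orientation), every array as its own observation, no centring, arrays scaled to the same spread, probes with all values, a replicate block, only the arrays of the drugs compared together with no channel term, forward or reversed 5-FU arrays alone without the channel term, single probes, robust moderation, a minimum absolute log2 ratio of 1, and leaving out each replicate, where the lone sample left is assumed to vary like the other groups.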

Results

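RNA from H460 cells, a human lung cancer line that carries wild-type p53, was compared on two-channel arrays after 24 h with 1 of 5 drugs and without drug. Per the labels, 5-fluorouracil (5-FU) was given at 1 µM, cytarabine at 0.2 µM, cisplatin at 5 µM, paclitaxel at 5 nM and cytochalasin D at 0.2 µM. There are 12 arrays. 5-FU was hybridised in both channel orientations (4 arrays, taken as 2 replicates of 2 orientations), and each other drug on 2 arrays with treated RNA in the same channel. The labels do not say whether replicates came from separate cultures or whether untreated RNA was shared between drugs. Each value is a log ratio within an array, taken as log2, so a ratio reads a gene relative to the other genes of that array.

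Arrays of the same drug resembled each other: across probes, Pearson's r between replicates was 0.713 to 0.819 for the 4 drugs hybridised in 1 orientation, and 0.627 to 0.678 between 5-FU arrays of the same orientation (genes are not independent replicates). Much of this likeness is not particular to a drug. Arrays of different drugs among cytarabine, paclitaxel and cytochalasin D correlated at 0.629 to 0.725, and cisplatin arrays with those at 0.349 to 0.442. Forward and reversed 5-FU arrays correlated at −0.527 to −0.488, so the deposited values are ratios of channels and were turned to treated over untreated. The direction used throughout, drug over untreated, is likely rather than stated: it was set so that MDM2, CDKN1A and the median of a fixed p53 target list are positive in 5-FU. The p53 list in 5-FU is therefore no independent evidence of a p53 response, and its direction is partly set in advance wherever 5-FU is compared with other drugs. Genes were tested with limma on 2 replicates per drug, with a term for the channel that only the 5-FU arrays can measure. "Rose" and "fell" are used for genes with adjusted p under 0.05, and errors are standard errors of the log2 ratio.

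5-FU raised HMOX1, which degrades haem, by 2.45 ± 0.08 (5.47-fold, adjusted p = 6.4e-07, n = 2 replicates and 4 arrays). This was the largest rise among tested genes changed the same way on each array. MDM2, the ubiquitin ligase that limits p53, rose by 1.48 ± 0.09 (adjusted p = 9.0e-06), DDB2, which recognises ultraviolet damage, by 0.82 ± 0.07, and the lysosomal activator GM2A by 1.62 ± 0.18. Among the same tested genes the largest fall was in SARM1, an NAD-cleaving enzyme, at −2.03 ± 0.06, followed by ASNS, which makes asparagine, at −1.93 ± 0.08. Among 3829 genes tested, 212 rose and 465 fell. Further rises were IER3 (1.60), GPRC5A (1.23) and TOB1 (1.09), and further falls EFEMP1 (−1.80), YWHAZ (−1.80), MTHFD2 (−1.78) and PYCR1 (−1.78), the last 2 being enzymes of mitochondrial folate and proline synthesis. Dropping the channel term let 5589 genes be tested and gave 377 rises and 750 falls, with 638 of the 677 calls kept. The term does not enter the 5-FU ratios, so the gain in calls is no measure of channel bias. With that term dropped and the 5-FU arrays fitted alone, 0 genes passed in limma, against 1250 with unadjusted p under 0.05.

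Of 11 p53 targets tested in 5-FU, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.24 and adjusted p = 0.000773 for the list (adjusted p = 0.302 with an estimated correlation). TP53I3 and TRIAP1 rose by 0.63 each and EI24 by 0.56, while CCNG1 fell by −0.24. EI24 and CCNG1 were chosen after their values were seen. Of 15 genes of G2 and mitosis, 6 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.000545, and adjusted p = 0.279 with an estimated correlation), led by the mitotic kinases AURKA (−1.67 ± 0.06) and AURKB (−0.91 ± 0.10) and by BIRC5 (−1.15 ± 0.06). All of these lists are tested against the other genes. TP53I3 lost its call without 5-FU replicate 1 (0.37), TRIAP1 without 5-FU replicate 2 (0.61), and CCNG1 without either (−0.26 and −0.23).

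Of 14 cytosolic ribosomal protein genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of −0.56 and adjusted p = 3.7e-14 (adjusted p = 0.152 with an estimated correlation). RPL10A (−1.53 ± 0.07), RPL3 (−1.45 ± 0.09) and RPL12 (−1.44 ± 0.08) fell most. Of 19 genes of the unfolded protein and amino acid response, 7 fell and 1 rose (10 and 2 adjusted over the list alone; median −0.16, adjusted p = 1.9e-07, and adjusted p = 0.291 with an estimated correlation), among them the cystine carrier SLC7A11 (−1.52 ± 0.08) and the chaperone HSP90B1 (−1.23). SLC3A2, chosen after its value was seen, rose by 0.28 (0.16 and no longer passing without 5-FU replicate 2). Among 11 heat shock genes 7 fell and 3 rose (7 and 3 adjusted over the list alone; median −0.65, adjusted p = 0.0125, adjusted p = 0.358 with an estimated correlation). HSPD1 (−1.51 ± 0.07) and CCT4 (−1.17 ± 0.08) fell, whereas BAG1 (0.79), HSPA8 (0.63) and HSPA6 (0.44), chosen after their values were seen, rose. Without the channel term the heat shock list no longer passed (adjusted p = 0.123), and HSPA6 lost its call without 5-FU replicate 2 (0.35) and with every array as its own observation (adjusted p = 0.0867).

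In the nucleotide list of 5-FU 6 of 14 fell and 1 rose (6 and 2 adjusted over the list alone; median −0.17, adjusted p = 0.0137, adjusted p = 0.291 with an estimated correlation), including IMPDH2 (−1.02), which commits purines to guanine nucleotides, and SHMT2 (−0.65). IMPDH1, chosen after its value was seen, rose by 0.38 and lost its call without either 5-FU replicate (0.44 and 0.32). The nucleotide list itself did not pass without the channel term (adjusted p = 0.0951) or without 5-FU replicate 2 (adjusted p = 0.0699). Of 13 hypoxia and glycolysis genes 6 fell and 0 rose (median −0.18, adjusted p = 0.0011, adjusted p = 0.177 with an estimated correlation), with PFKP at −1.07, GPI at −0.90 and HIF1A at −0.84. Of 23 actin and SRF target genes 10 fell and 1 rose (13 and 2 adjusted over the list alone; median −0.30, adjusted p = 0.00147, adjusted p = 0.291 with an estimated correlation): the matricellular gene CCN2 fell by −1.34 ± 0.06, MYL12A by −0.91 and ACTB by −0.39 ± 0.06, while MYL6, chosen after its value was seen, rose by 0.42. H2AZ2 (−1.12) and H3-3B (−0.68) are the 2 of 3 histone genes that fell (adjusted p = 0.0469 for the list, adjusted p = 0.358 with an estimated correlation), a list call that ended without any replicate of the other 4 drugs (adjusted p = 0.0566 to 0.0928) and with every array as its own observation (adjusted p = 0.179). VIM (−1.36), FN1 (−0.91) and the repair genes PARP1 (−0.92), MSH6 (−0.91) and APEX1 (−0.88) fell as well. In the test against other genes the repair list did not pass with the channel term (adjusted p = 0.0872) and passed without it (adjusted p = 0.0037). TUBB did not change detectably (−0.15 ± 0.06, adjusted p = 0.137).

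Cytarabine lowered SLA, an adaptor of receptor signalling, by −2.91 ± 0.21 (adjusted p = 0.000171, n = 2). It lowered SWT1, an RNA endonuclease of nuclear quality control, by −2.66 ± 0.09, the metalloprotease ADAM12 by −2.62 ± 0.12 and the complement gene C8B by −2.56 ± 0.16. ADH4 (−2.22 ± 0.16), UGT1A10 (−2.08 ± 0.09) and CPVL (−2.06 ± 0.11) fell too, as did ATM, the kinase that signals double-strand breaks (−1.55 ± 0.11). SLA, SWT1, C8B, UGT1A10 and ATM also fell in paclitaxel and cytochalasin D. For such shared falls faint spots, shared untreated RNA and a channel bias of these arrays stay open beside a drug effect. Among 4683 genes tested 655 rose and 599 fell. Without cytarabine replicate 2 the total of 1254 became 641. Rises no longer outnumbered falls without the channel term: of 6637 genes tested 784 rose and 1061 fell, and 391 of the 655 rises kept their call. Of 14 ribosomal protein genes 10 fell and 0 rose (10 and 0 adjusted over the list alone; median −0.38, adjusted p = 3.8e-05, adjusted p = 0.152 with an estimated correlation), with RPS4X at −0.62 ± 0.11 and RPL10A at −0.54 (−0.36 without the channel term, where with cytarabine fitted alone it did not pass, adjusted p = 0.0564).

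MDM2 did not change detectably with cytarabine (0.02 ± 0.11, adjusted p = 0.909; −0.21 without the channel term, also not passing). The p53 list showed 2 rises, CYFIP2 (0.40) and TNFRSF10C (0.29), and 2 falls, XPC (−0.63) and CCNG1 (−0.32) (median 0.00 over 14 genes, adjusted p = 0.878). Cell cycle genes moved in both directions: of 22 in the G2 and mitosis list 6 fell and 5 rose (adjusted p = 0.757). AURKA (−0.82 ± 0.08), TOP2A (−0.79 ± 0.10) and PLK1 (−0.74 ± 0.07) fell, while the transcription factor FOXM1 rose by 0.64 ± 0.12. The other rises, chosen after their values were seen, were CENPA (0.64; 0.31 without the channel term, where with cytarabine fitted alone it did not pass), KIF2C (0.63), MAD2L1 (0.61, but −0.10 without the channel term) and STMN1 (0.28). CCNE1 (−0.96 ± 0.13) and the primase gene PRIM1 (−0.82 ± 0.09) fell. TK1, the thymidine kinase, rose by 0.52 ± 0.12, and SLC29A1, a nucleoside carrier that takes up cytarabine, fell by −0.72 ± 0.08. The growth factor receptor TGFBR2 (−1.31 ± 0.13), the phosphatase DUSP6 (−1.28 ± 0.11), the pyruvate dehydrogenase kinase PDK1 (−1.51 ± 0.12) and the kinase SGK1 (−0.98 ± 0.13) fell. VEGFB (1.16 ± 0.14; 0.76 without the channel term) and PLEC (1.04 ± 0.16) rose. The rise fitted for CX3CL1, 0.99, comes mostly from the channel term, since its arrays read 0.07 and 0.19; it did not pass without that term (0.13). Calls ended without cytarabine replicate 1 for TK1 (0.49), TNFRSF10C (0.26), XPC (−0.57), CYFIP2 (0.29) and STMN1 (0.22), and without cytarabine replicate 2 for TK1 (0.55), CCNG1 (−0.26), CYFIP2 (0.51), STMN1 (0.34) and KIF2C (0.48). Leaving out 5-FU replicate 1 ended those of CCNG1 (−0.23), CYFIP2 (0.23) and STMN1 (0.26), and 5-FU replicate 2 those of TNFRSF10C (0.23) and STMN1 (0.30). CYFIP2 also missed the threshold without either cisplatin replicate (0.40), with every array as its own observation (adjusted p = 0.097) and without the channel term (0.16, adjusted p = 0.253). Scaling the arrays ended its call (0.36) and that of STMN1 (0.25). TUBB fell by −0.28, a call that ended without the channel term (−0.14), 5-FU replicate 2 (−0.20) or either cytarabine replicate (−0.29 and −0.26), with scaled arrays (−0.24) and with every array as its own observation (adjusted p = 0.064). ACTB read −0.02 (adjusted p = 0.822), but −0.26 without the channel term, where it passed. CCNG1 read −0.54 there.

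Cisplatin raised MDM2 by 2.89 ± 0.11 (adjusted p = 8.6e-06, n = 2). It raised TNFAIP3, an inhibitor of NF-kB signalling, by 2.49 ± 0.11, the thioredoxin inhibitor TXNIP by 2.12 ± 0.10 and DDB2 by 1.89 ± 0.09. RGS2 (1.85 ± 0.06) and the p53-induced phosphatase PPM1D (1.74 ± 0.14) also rose, and ADAM12 (−1.83), CPVL (−1.74), SLA (−1.54) and SWT1 (−1.54) fell most. ADAM12, CPVL, SLA and SWT1 fell in cytarabine and paclitaxel as well. Their falls are therefore not particular to cisplatin, and the causes left open for falls shared with cytarabine apply to them. Among 4883 genes 540 rose and 480 fell. The balance turned without the channel term, with 490 higher and 663 lower of 7146 tested, and 226 of the 540 rises kept their call. Without cisplatin replicate 1 the total of 1020 became 473, and without cisplatin replicate 2 it became 502. Of 14 p53 targets 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.86 and adjusted p = 1.1e-22 (adjusted p = 0.152 with an estimated correlation). They include the death receptor FAS (1.44 ± 0.15), XPC (1.41), EI24 (0.94), PMAIP1 (0.86) and CCNG1 (0.85), all but FAS chosen after their values were seen.

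In the NF-kB list of cisplatin TNFAIP3, IL6 (1.67 ± 0.10), CXCL8 (1.40 ± 0.08) and PLAU (1.25 ± 0.13) are the 4 of 17 that rose, with 0 falls (6 and 1 adjusted over the list alone; median 0.21, adjusted p = 1.7e-06, adjusted p = 0.358 with an estimated correlation). In the immediate early list 5 of 13 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.0211, adjusted p = 0.291 with an estimated correlation): FOSL2 (1.53 ± 0.18), KLF10 (1.44 ± 0.17), IER3 (1.21 ± 0.08), and, chosen after their values were seen, NR4A1 (0.58) and DUSP2 (0.38), against DUSP6 (−0.72 ± 0.12). This list did not pass without cisplatin replicate 2 (adjusted p = 0.0808) or 5-FU replicate 1 (adjusted p = 0.0784). NR4A1 lost its call without cisplatin replicate 1 (0.50), and DUSP2 without any of 7 replicates, from 0.03 without 5-FU replicate 2 to 0.45 without cisplatin replicate 1, while it read 0.73 without 5-FU replicate 1. Its call also ended without the channel term (0.15, adjusted p = 0.283) and with every array as its own observation (adjusted p = 0.307). DUSP6 read −0.45 without the channel term and passed. Amino acid response genes fell, 8 of 21 against 1 rise (9 and 1 adjusted over the list alone; median −0.18, adjusted p = 0.00027, adjusted p = 0.291 with an estimated correlation), with ASNS (−0.86 without the channel term) and SLC7A11 at −1.36 ± 0.10 each. The rise, AARS1 (0.59), read −0.10 without the channel term, and did not pass without 5-FU replicate 2 (0.51), cisplatin replicate 1 (0.50) or cisplatin replicate 2 (0.69), or without any paclitaxel or cytochalasin D replicate (0.59), or with every array as its own observation (adjusted p = 0.0849). The replication protein RPA2 (1.15 ± 0.13), KIF2C (0.92 ± 0.12) and ALDH3A1 (1.01 ± 0.14) rose, while TOP2A (−0.94 ± 0.10) and CCN2 (−1.11 ± 0.07) fell. MAPK6 has a fitted rise of 1.88 with array values of 0.18 and 0.06, and did not pass without the channel term (0.12). TUBB did not change detectably (0.02 ± 0.07, adjusted p = 0.877). Neither did ACTB (−0.05 ± 0.07, adjusted p = 0.657), though without the channel term it read −0.28 and passed (adjusted p = 0.022).

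Paclitaxel lowered C8B by −2.30 ± 0.16, SLA by −2.02 ± 0.21, SWT1 by −1.84 ± 0.09 and UGT1A10 by −1.69 ± 0.10 (n = 2 each). PZP (−1.67), ADAM12 (−1.66), ADH4 (−1.64), CPVL (−1.63) and ATM (−1.24 ± 0.11) fell as well. The causes left open for falls shared with cytarabine apply here too. Among 4796 genes 193 rose and 283 fell. The total of 476 became 151 without paclitaxel replicate 1 and 268 without paclitaxel replicate 2. Dropping the channel term left 139 genes higher and 573 lower of 6974 tested, and 50 of the 193 rises kept their call. In the tubulin list, which holds the drug's target, TUBB2A rose by 0.63 ± 0.14 and 0 of the 13 genes fell (median 0.14, adjusted p = 0.514); TUBB read 0.14 ± 0.07 (adjusted p = 0.272), and without the channel term 0.28, where it passed (adjusted p = 0.0342). The TUBB2A call ended without the channel term (0.44) and without paclitaxel replicate 1 (0.79), paclitaxel replicate 2 (0.46), 5-FU replicate 2 (0.56) or either cisplatin replicate (0.63). The mitotic genes TOP2A (−0.76 ± 0.10) and AURKA (−0.68 ± 0.08) fell, as did DUSP6 (−1.17 ± 0.12) and PDK1 (−0.90 ± 0.12). MDM2 did not change detectably (0.06 ± 0.11, adjusted p = 0.732; −0.17 without the channel term, also not passing).

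Of 13 sterol genes, 3 rose with paclitaxel: CYP51A1 (0.73 ± 0.07; 0.35 without the channel term), TM7SF2 (0.41 ± 0.07) and LSS (0.37 ± 0.09), with 0 falls (4 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.0358, adjusted p = 0.548 with an estimated correlation). Without the channel term the list had adjusted p = 0.214, with every array as its own observation adjusted p = 0.113, without 5-FU replicate 2 adjusted p = 0.514, without paclitaxel replicate 1 adjusted p = 0.0692 and without paclitaxel replicate 2 adjusted p = 0.142. It also missed the threshold without any cytarabine or cytochalasin D replicate (adjusted p = 0.0511 to 0.0615). TM7SF2 lost its call without paclitaxel replicate 1 (0.32), and LSS without paclitaxel replicate 1 (0.38), paclitaxel replicate 2 (0.35), 5-FU replicate 2 (0.36) or the channel term (0.24, adjusted p = 0.0884), and with every array as its own observation (adjusted p = 0.0513). In the growth factor, receptor and matrix list TGFBR2 (−1.36 ± 0.13), the gelatinase MMP9 (−1.14 ± 0.18) and IGFBP3 (−0.38) are the 3 of 19 that fell, and ID1 (0.39) rose (3 and 1 adjusted over the list alone; median −0.13, adjusted p = 0.0479, adjusted p = 0.373 with an estimated correlation; adjusted p = 0.388 without the channel term). This list missed the threshold with every array as its own observation (adjusted p = 0.504) or arrays scaled to the same spread (adjusted p = 0.0613), without 5-FU replicate 2 (adjusted p = 0.503) and without any cisplatin, paclitaxel or cytochalasin D replicate (adjusted p = 0.056 to 0.0751). MMP9 missed the threshold without 5-FU replicate 2 (−1.06), IGFBP3 without 5-FU replicate 1 (−0.22), paclitaxel replicate 1 (−0.40) or paclitaxel replicate 2 (−0.35), and ID1 without 5-FU replicate 1 (0.13), paclitaxel replicate 1 (0.36) or paclitaxel replicate 2 (0.42). The call of ID1 also ended without the channel term (0.11, adjusted p = 0.437) and with scaled arrays (0.34), and those of ID1 and IGFBP3 with every array as its own observation (adjusted p = 0.224 and 0.0872). MMP9 read −0.71 without the channel term and passed. UNC5B and MATCAP2 have fitted rises of 1.81 and 1.19, with array values of 0.42 and 0.29 and of 0.11 and 0.01; neither passed without the channel term (0.36 and 0.06).

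Cytochalasin D, which blocks actin polymerisation, raised the actin genes ACTG2 (1.11 ± 0.15), ACTG1 (1.03 ± 0.07, adjusted p = 0.00017) and ACTB (0.47 ± 0.07, adjusted p = 0.0063; n = 2 each). CCN2 and CCN1, matricellular genes that respond to cell tension, fell by −1.82 ± 0.07 and −1.11 ± 0.07. TAGLN2 (−0.44) and RND3 (−0.41), chosen after their values were seen, complete the 3 rises and 4 falls among 25 actin and SRF targets (5 and 6 adjusted over the list alone; median −0.01, adjusted p = 0.493). Without the channel term ACTG2 read 0.59 and ACTB 0.24. With every array as its own observation CCN1 read −0.72 and did not pass. ACTB missed the threshold without cytochalasin D replicate 2 (0.40), and TAGLN2 and RND3 without cytochalasin D replicate 1 (−0.41 and −0.36) or cytochalasin D replicate 2 (−0.46 each).

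Among 4835 genes tested with cytochalasin D 306 rose and 367 fell, and the total of 673 became 207 without cytochalasin D replicate 1 and 243 without cytochalasin D replicate 2. A fit without the channel term had 183 higher and 640 lower of 7026 tested, and 70 of the 306 rises kept their call. C8B (−2.40), SLA (−2.13), UGT1A10 (−1.96 ± 0.10), SWT1 (−1.67) and ATM (−1.24 ± 0.11) fell, as they did with cytarabine and paclitaxel, and the same causes stay open. The exonuclease EXO1 (−0.97 ± 0.08), the interferon-induced gene IFI35 (−1.03 ± 0.14) and PRIM1 (−0.89 ± 0.09) fell as well. TNFAIP3 (0.87 ± 0.11), FKBP9 (1.11 ± 0.09) and HMOX1 (0.74 ± 0.10) rose, each by less without the channel term (0.54, 0.63 and 0.42). In the nucleotide list 5 of 16 fell and 0 rose (5 and 0 adjusted over the list alone; median −0.19, adjusted p = 0.0125, adjusted p = 0.152 with an estimated correlation; adjusted p = 0.439 without the channel term and 0.486 with every array as its own observation): PFAS (−0.58 ± 0.11), IMPDH2 (−0.54 ± 0.11), TK1 (−0.52 ± 0.12), SLC29A1 (−0.44 ± 0.08) and, chosen after its value was seen, CAD (−0.34). Each of these 5 lost its call without cytochalasin D replicate 1 (−0.62, −0.52, −0.35, −0.47 and −0.35 in that order). All but TK1 also lost it without cytochalasin D replicate 2 (−0.53, −0.57, −0.41 and −0.33), and without 5-FU replicate 1 PFAS (−0.44), TK1 (−0.45) and SLC29A1 (−0.24) did. CAD missed the threshold also without 5-FU replicate 2 (−0.27) or any cisplatin or paclitaxel replicate (−0.34). The calls of IMPDH2 (−0.27, adjusted p = 0.121), TK1 (−0.28, adjusted p = 0.139) and CAD (−0.10, adjusted p = 0.491) ended without the channel term, where SLC29A1 read −0.27 and passed. With every array as its own observation those of IMPDH2, SLC29A1 and CAD did (adjusted p = 0.0543, 0.092 and 0.0987). In the heat shock list HSPA6 (0.86 ± 0.09) and HSPA8 (0.66 ± 0.09) rose and CCT6A (−0.37) and CCT5 (−0.31) fell (15 genes, adjusted p = 0.912). HSPA6 read 0.38 without 5-FU replicate 2, where it did not pass, and 1.33 without 5-FU replicate 1. The rises of HSPA6 and HSPA8 were 0.44 and 0.37 without the channel term. CCT6A and CCT5 did not pass without cytochalasin D replicate 1 (−0.35 and −0.26), cytochalasin D replicate 2 (−0.39 and −0.36) or 5-FU replicate 1 (−0.29 each), nor CCT5 without the channel term (−0.20). With every array as its own observation HSPA6, CCT6A and TUBB did not pass (adjusted p = 0.103, 0.0605 and 0.0672). TUBA4A (−0.58 ± 0.10) and TUBB (−0.32 ± 0.07) are the 2 of 13 tubulin list genes that fell, with 0 rises (adjusted p = 0.912). TUBB lost its call without the channel term (−0.18), 5-FU replicate 2 (−0.24), cytochalasin D replicate 1 (−0.24) or cytochalasin D replicate 2 (−0.40), and TUBA4A without cytochalasin D replicate 1 (−0.53).

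**Figure D1:**
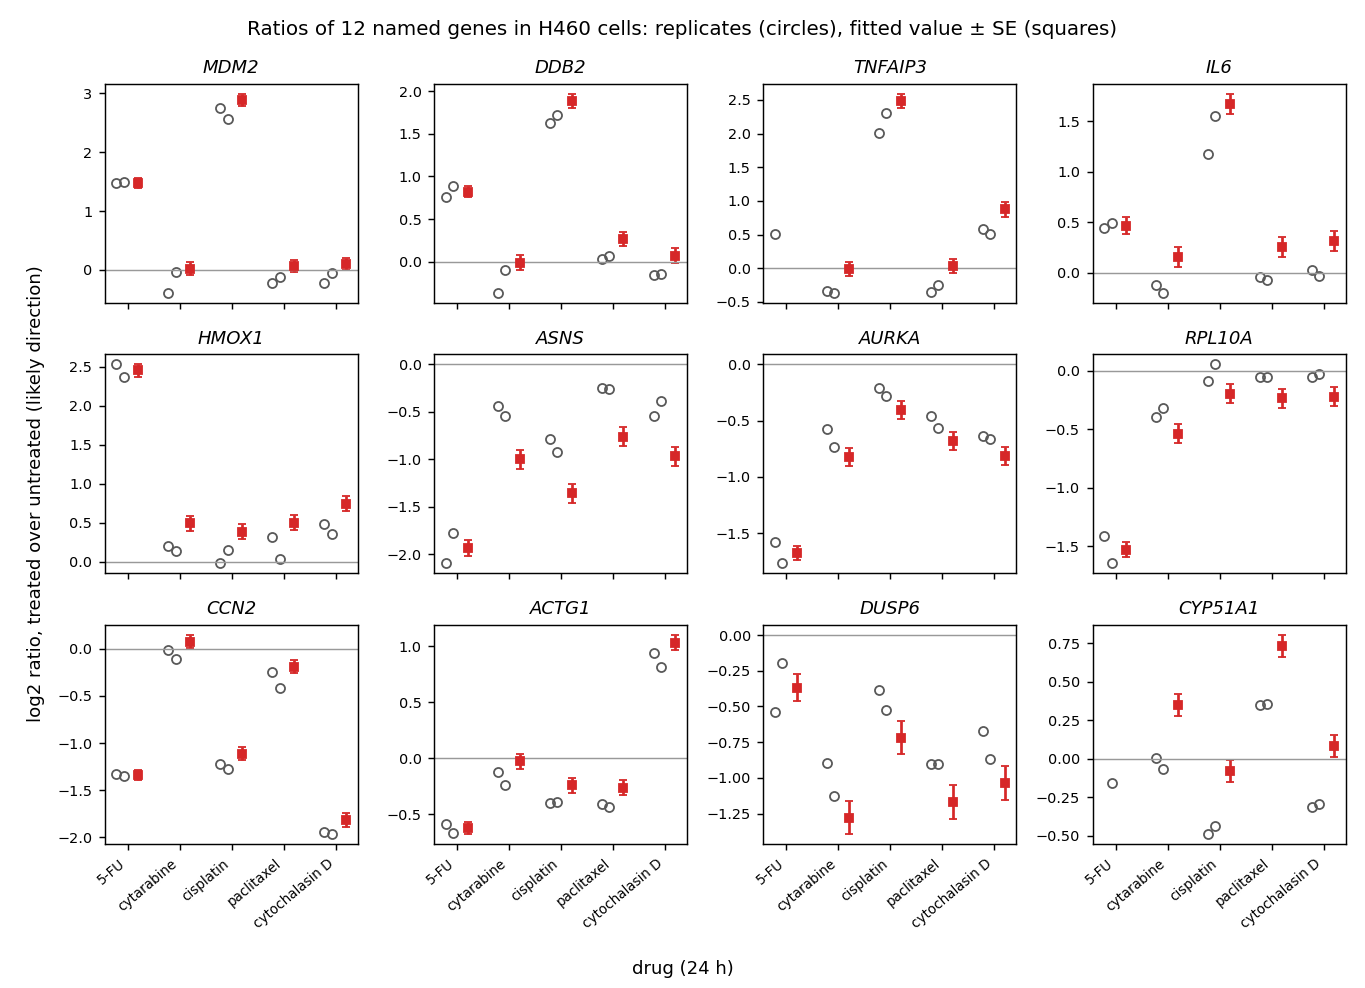
Log2 ratios of drug over untreated for 12 named genes: circles are replicates before the channel term, squares the limma fit with it and its standard error (n = 2 per drug; likely direction).

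The 2 antimetabolites differed in 818 of 3574 genes, 298 higher and 520 lower in 5-FU than in cytarabine (536 in all without cytarabine replicate 2). UGT1A10 (2.48 ± 0.12), MRNIP (2.46 ± 0.13), PZP (2.24 ± 0.17), ADH4 (2.09 ± 0.20) and CBLB (1.99 ± 0.16) were the highest in 5-FU relative to cytarabine. UGT1A10 and ADH4 fell in cytarabine, which accounts for most of their differences. UGT1A10, ADH4 and PZP also fell in paclitaxel, so these differences are not particular to the 2 antimetabolites. Only 5-FU was hybridised in both orientations, and the channel effect does not cancel in this comparison. A channel bias particular to the cytarabine arrays therefore cannot be told apart from a difference between the drugs. PYCR1 (−2.18 ± 0.26; −1.35 without 5-FU replicate 1), SARM1 (−1.97 ± 0.09), EFEMP1 (−1.75 ± 0.08), ASPH (−1.72 ± 0.28; −1.07 without the channel term) and MTHFD2 (−1.68 ± 0.12) were the most lowered. Among 10 p53 targets, MDM2 (1.46 ± 0.13), DDB2 (0.83 ± 0.11) and SAT1 (0.45 ± 0.11) were higher and CYFIP2 (−0.48) and TNFRSF10C (−0.26) lower (5 and 2 adjusted over the list alone; median 0.39, adjusted p = 0.0327, adjusted p = 0.516 with an estimated correlation). All of these but MDM2 were chosen after their values were seen. SAT1 lost its call without either 5-FU replicate (0.46 and 0.44) or cytarabine replicate 1 (0.34). CYFIP2 and TNFRSF10C lost theirs without 5-FU replicate 1 (−0.37 and −0.33), 5-FU replicate 2 (−0.59 and −0.19), cytarabine replicate 1 (−0.37 and −0.23) or cytarabine replicate 2 (−0.59 and −0.28). CYFIP2 also missed the threshold without any cisplatin or paclitaxel replicate (−0.48), and TNFRSF10C without either cytochalasin D replicate (−0.26). CYFIP2 read −0.25 without the channel term and did not pass (adjusted p = 0.222). Its call ended too with values not centred (−0.47) and with every array as its own observation (adjusted p = 0.0743), and scaling the arrays ended it (−0.45) and that of TNFRSF10C (−0.22).

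Actin and SRF targets were lower in 5-FU than in cytarabine, 9 of 21 against 1 higher (11 and 2 adjusted over the list alone; median −0.31, adjusted p = 0.0311, adjusted p = 0.516 with an estimated correlation; adjusted p = 0.166 without the channel term). CCN2 (−1.42 ± 0.09) was the lowest and MYL6 (0.62 ± 0.09) the higher gene, both chosen after their values were seen. In the amino acid response list 8 of 19 were lower and 1 higher (9 and 3 adjusted over the list alone; median −0.17, adjusted p = 0.0327, adjusted p = 0.520 with an estimated correlation). AARS1 (−1.29 ± 0.21; −0.60 and not passing without the channel term) and ASNS (−0.94 ± 0.13; −1.44 without the channel term) were lower, and ATF6 (0.38 ± 0.09) was higher, all 3 likewise chosen, but ATF6 did not pass without the channel term (0.19), 5-FU replicate 1 (0.24) or cytarabine replicate 1 (0.35), or with every array as its own observation (adjusted p = 0.0845). In the test against other genes the lists of G2 and mitosis, histones, NF-kB and ribosomal proteins did not pass with the channel term. They passed without it (adjusted p = 0.00105, 0.00194, 0.0168 and 0.0222).

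Between the cytoskeletal drugs, CCN2 was higher in paclitaxel than in cytochalasin D by 1.62 ± 0.08 (adjusted p = 0.0001), and ACTG1 lower by −1.30 ± 0.08 (adjusted p = 0.00025). BRAP, a regulator of RAS signalling, was higher by 1.41 ± 0.11 (adjusted p = 0.00082). Among 4743 genes 12 were higher and 9 lower in paclitaxel, against 640 with unadjusted p under 0.05. CCN1 (1.19 ± 0.07), IFI35 (0.98 ± 0.14) and TUBA4A (0.90 ± 0.11) were also higher, and MRNIP (−0.91 ± 0.12), HSPA6 (−0.85 ± 0.10), TNFAIP3 (−0.84 ± 0.11) and HSPA8 (−0.84 ± 0.11) lower. CCN1 and IFI35 kept their sizes (1.19 and 0.98) but did not pass without the channel term (adjusted p = 0.447 and 0.163). With every array as its own observation CCN1, IFI35, MRNIP, HSPA6 and TNFAIP3 did not pass (adjusted p = 0.394, 0.128, 0.172, 0.461 and 0.201). Without paclitaxel replicate 1 the total of 21 became 7, without cytochalasin D replicate 1 it became 11 and without cytochalasin D replicate 2 it became 9. Leaving out paclitaxel replicate 1 ended the calls of IFI35 (0.91), TUBA4A (0.85), MRNIP (−0.90), HSPA6 (−0.84), TNFAIP3 (−0.80) and HSPA8 (−0.79), and so did leaving out paclitaxel replicate 2 (1.05, 0.95, −0.93, −0.87, −0.89 and −0.89 in that order). Leaving out cytochalasin D replicate 2 ended the same 6 (0.83, 0.96, −0.87, −0.73, −0.88 and −0.83). Cytochalasin D replicate 1 decided all of them but HSPA6 (1.13, 0.85, −0.96, −0.81 and −0.84 without it), and either cisplatin replicate that of IFI35 (0.98).

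The DNA-directed drugs (5-FU, cytarabine and cisplatin) differed from the cytoskeletal drugs (paclitaxel and cytochalasin D) in MDM2, higher by 1.38 ± 0.08, and in the stress gene IER3, higher by 1.27 ± 0.06. Cytarabine does not share these differences throughout: MDM2 read 0.02 in cytarabine against 0.06 in paclitaxel, and UGT1A10 −2.08 against −1.69. ALDH3A1 (0.85 ± 0.10), UGT1A10 (0.84 ± 0.07) and FOSL2 (0.80 ± 0.13) were higher, and SLC7A11 (−0.83 ± 0.07), SARM1 (−0.72 ± 0.06) and EIF3E (−0.70 ± 0.06) lower. SARM1, like ASPH, PYCR1 and MTHFD2 below, was among the genes most lowered in 5-FU relative to cytarabine. Cytarabine therefore did not share these differences to the same extent. ASPH (−0.77 ± 0.17) and PYCR1 (−0.71 ± 0.16; −0.43 without 5-FU replicate 1) were lower too, but neither passed without cisplatin replicate 2 (−0.68 and −0.71), paclitaxel replicate 1 (−0.69 and −0.76), cytochalasin D replicate 1 (−0.78 and −0.69) or cytochalasin D replicate 2 (−0.75 and −0.72). PYCR1 also missed the threshold without either cytarabine replicate (−0.70 and −0.72), cisplatin replicate 1 (−0.70) or paclitaxel replicate 2 (−0.65). ASPH did not pass without the channel term either (−0.55, adjusted p = 0.102), nor did ASPH and PYCR1 with every array as its own observation (adjusted p = 0.0647 and 0.178). Among 3536 genes 112 were higher and 176 lower. Standard errors and p values of this contrast come from the spread between replicates of a drug, not between drugs. They hold for these 5 drugs and not for the classes. Of 10 p53 targets 5 were higher and 0 lower (7 and 0 adjusted over the list alone; median 0.29, adjusted p = 1.5e-14, adjusted p = 0.0496 with an estimated correlation): MDM2, DDB2 (0.73 ± 0.06), SAT1 (0.65 ± 0.06), PPM1D (0.62 ± 0.10) and CCNG1 (0.27 ± 0.06), the last 4 chosen after their values were seen. The direction of this list is partly set by the sign chosen for 5-FU. Of 14 ribosomal protein genes 10 were lower and 0 higher (12 and 0 adjusted over the list alone; median −0.23, adjusted p = 4.5e-12, adjusted p = 0.0329 with an estimated correlation). CCNG1 did not pass without 5-FU replicate 1 (0.24), nor without any paclitaxel or cytochalasin D replicate (0.27).

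In the same contrast IER3 and FOSL2 are the 2 of 11 immediate early genes that were higher, with 0 lower (5 and 1 adjusted over the list alone; median 0.17, adjusted p = 4.0e-06, adjusted p = 0.0989 with an estimated correlation). CXCL8 (0.72 ± 0.06), CXCL10 (0.63 ± 0.16) and IL6 (0.48 ± 0.07), chosen after their values were seen, are the 3 of 10 NF-kB genes that were higher, with 0 lower (5 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.000825, adjusted p = 0.174 with an estimated correlation). SLC7A11, MTHFD2 (−0.61 ± 0.07), ASNS (−0.57 ± 0.07) and HSP90B1 (−0.54 ± 0.05) are the 4 of 19 amino acid response genes that were lower, with 0 higher (5 and 0 adjusted over the list alone; median −0.10, adjusted p = 0.000825, adjusted p = 0.241 with an estimated correlation); the last 3 were chosen after their values were seen. APEX1 (−0.59 ± 0.05), PMS2 (−0.28), MSH6 (−0.26) and PARP1 (−0.25), likewise chosen, are the 4 of 12 repair genes that were lower, with 0 higher (4 and 0 adjusted over the list alone; median −0.02, adjusted p = 0.03, adjusted p = 0.296 with an estimated correlation; adjusted p = 0.623 without the channel term). Leaving out 1 replicate at a time ended the call of CXCL10 in 8 of 10 cases (0.48 to 0.72), of MSH6 in 6 (−0.26 to −0.21), of PMS2 in 6 (−0.29 to −0.16) and of PARP1 in 9 (−0.27 to −0.19). Those of CXCL10 (0.61), PMS2 (−0.24) and PARP1 (−0.24) also ended without the channel term. With every array as its own observation PMS2 and MSH6 did not pass (adjusted p = 0.369 and 0.0626), and with scaled arrays PMS2 did not (−0.18). In the test against other genes the histone list did not pass with the channel term and passed without it (adjusted p = 0.0184).

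Differences in the p53 list were also tested between pairs of drugs, a choice made after the data were seen. The list was higher in cisplatin than in cytarabine (9 of 14 genes lower in cytarabine, median −0.96, adjusted p = 1.0e-20, adjusted p = 0.178 with an estimated correlation), paclitaxel (9 of 13 higher in cisplatin, median 1.05, adjusted p = 4.4e-29, adjusted p = 0.0691 with an estimated correlation) and cytochalasin D (11 of 14 higher in cisplatin, median 1.13, adjusted p = 7.2e-34, adjusted p = 0.0592 with an estimated correlation). It was lower in 5-FU than in cisplatin (7 of 10 genes, median −0.67, adjusted p = 9.4e-06, adjusted p = 0.199 with an estimated correlation). Ribosomal protein genes were lower in cytarabine than in cisplatin (10 of 14, median −0.35, adjusted p = 0.00626, adjusted p = 0.178 with an estimated correlation). Over the 5 drugs and 23 lists, 17 of 115 tests against untreated RNA passed with the preset correlation, 5 up and 12 down, and 0 with an estimated correlation; fry, whose p tests whether a list's genes move on balance one way, passed 51. The fit without the channel term passed 16, among them 4 new ones: repair in 5-FU, replication in cisplatin (up, adjusted p = 0.0102), and ribosome biogenesis in paclitaxel and cytochalasin D (down, adjusted p = 0.0128 and 0.00117).

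**Figure D2:**
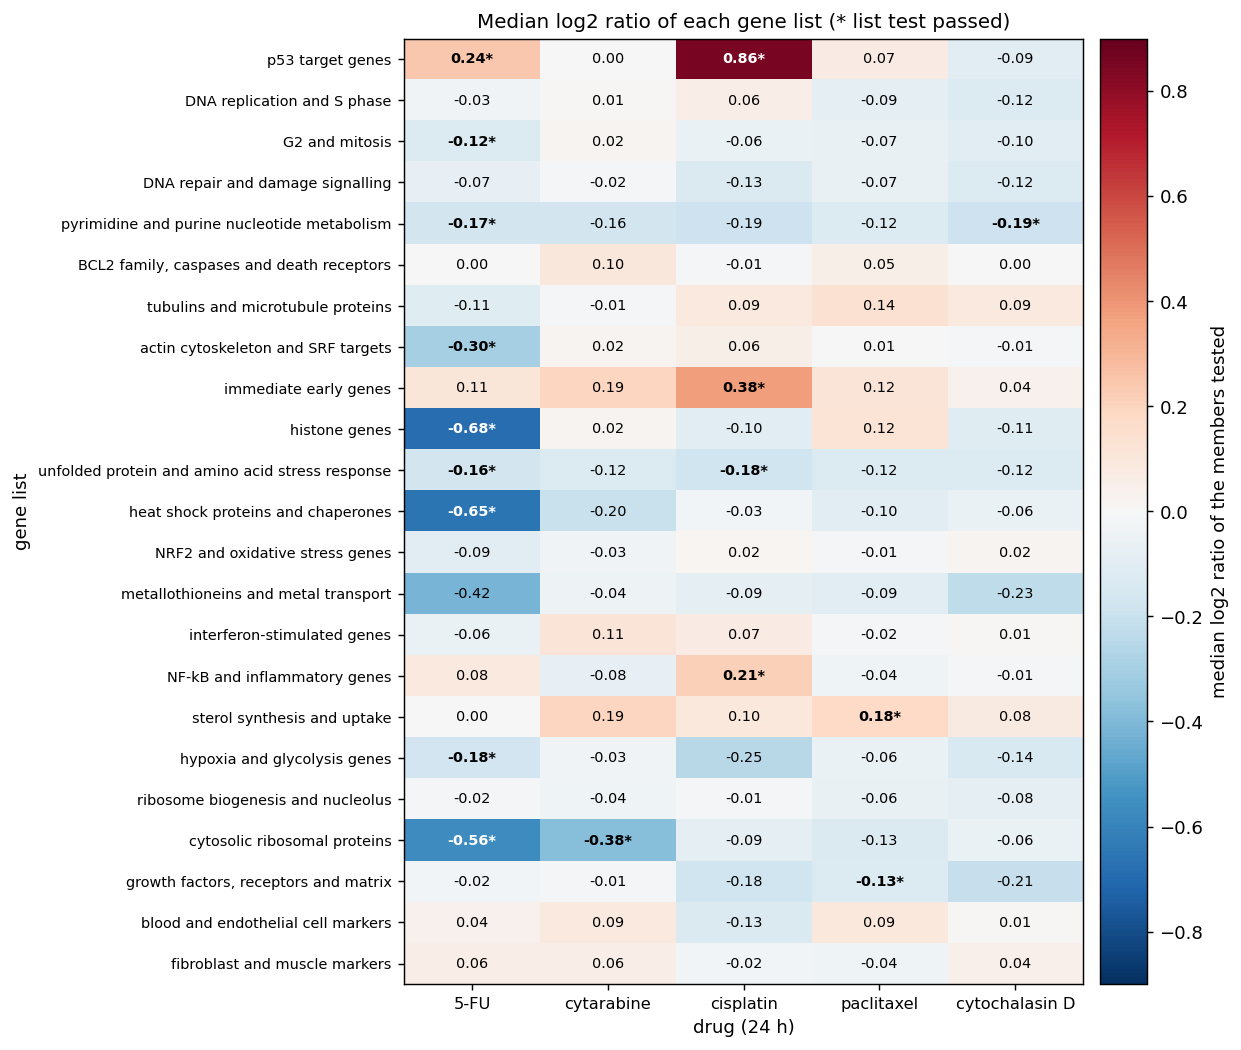
Median log2 ratio of each fixed gene list in each drug, with the lists that passed the test against other genes marked.

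Across the 3536 genes with a fitted value in every drug, cytarabine and paclitaxel were the most alike (Pearson's r = 0.78, covariance 0.0591), followed by paclitaxel and cytochalasin D (0.73, covariance 0.0438) and cytarabine and cytochalasin D (0.68, covariance 0.0543). Cisplatin correlated with paclitaxel at 0.54, with cytochalasin D at 0.50 and with cytarabine at 0.38, and 5-FU with the others at 0.16 to 0.22. Simulated values with no drug effect gave r = 0.538 (highest 0.586) for drugs that share the channel estimate, which accounts for a covariance of 0.0097. That r comes from noise alone, so it is no baseline for values that hold drug effects. With 0.0097 taken off, the first 3 pairs kept covariances of 0.0494, 0.0341 and 0.0446, and cisplatin's 3 pairs 0.0263 to 0.0282. Without the channel term their r was 0.78, 0.70 and 0.67, and 0.33 to 0.43 (4991 genes). These values argue against the shared channel estimate as the whole cause of these correlations. SLA, SWT1, C8B, UGT1A10 and ATM are among 180 genes that fell in cytarabine, paclitaxel and cytochalasin D alike, and 91 rose in all 3. In the fit without the channel term 376 fell and 13 rose in all 3, and 113 of the 180 falls but 3 of the 91 rises were called in both fits. Cytarabine and paclitaxel shared 146 rises (26.2 if independent) and 232 falls (34.8), paclitaxel and cytochalasin D 110 (12.2) and 199 (21.2), and cytarabine and cytochalasin D 165 (41.9) and 254 (45.5). These drugs share the channel estimate, so independence is not the value expected without a drug effect. Without the channel term, which leaves any channel bias in all 3 drugs, the shared rises and falls were 69 (15.9) and 479 (84.3), 25 (3.50) and 407 (51.4), and 51 (20.5) and 482 (97.4). Untreated RNA could not be split between drugs either, so part of the excess may come from the shared controls or the shared channel estimate. Cytarabine and paclitaxel differed in 3 of 4634 genes (904 with unadjusted p under 0.05), cytarabine and cytochalasin D in 303. 5-FU and cisplatin shared 52 rises (19.5) and 94 falls (43.7), while 76 genes called in both went opposite ways.

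**Figure D3:**
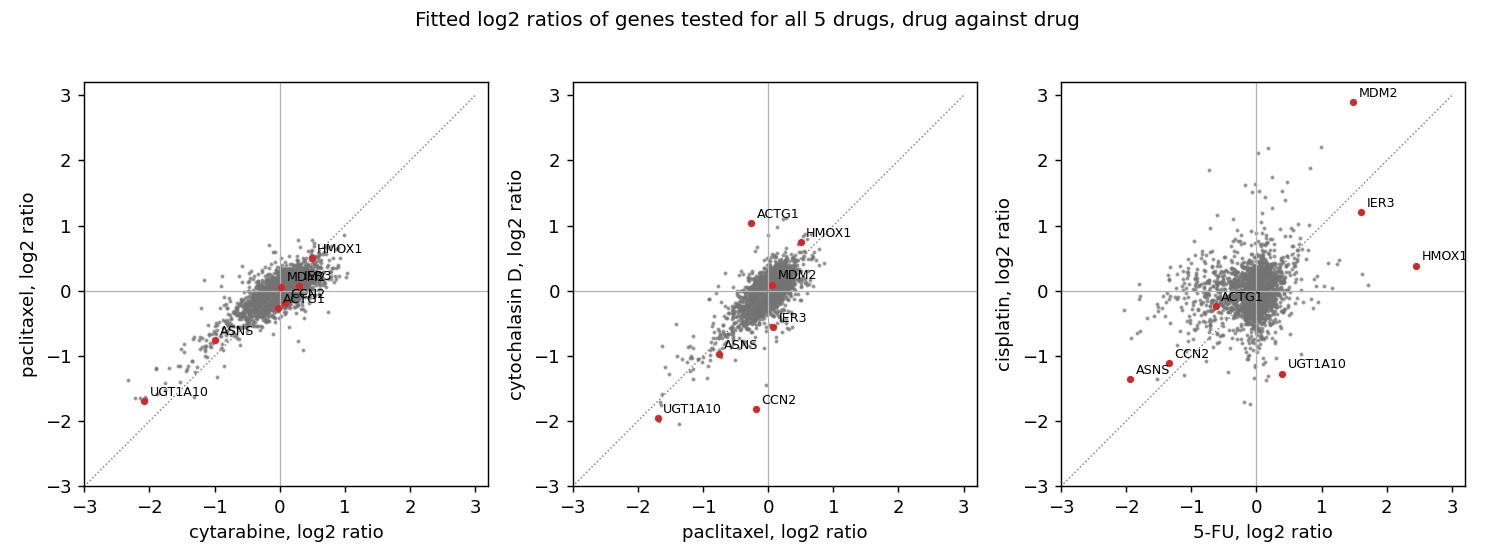
Fitted log2 ratios of pairs of drugs against each other, 1 point per gene.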

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

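The tests of channel bias, faint spots, a common response and noise in the channel effect, the tests within each drug and the counts without the channel term below were chosen only after the result was seen; the counts of other splits were planned.

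GPI, the glycolytic isomerase, read −0.72 on the forward array of 5-FU replicate 2 and −0.94 to −0.96 on the other 3 5-FU arrays; this array lies far from the others for that gene. It is 1 of 57 named genes tested on 4 arrays, and chance marks about 1 in 20, so this is fewer than chance gives.

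Some genes were not tested for lack of 5-FU values, yet read far from 0 without the channel term: HMGB2 and H1-10 have both orientations in only 1 5-FU replicate, and the others have no channel effect (10 genes in 11 combinations with a drug, each over 1.5 in absolute log2 ratio and with adjusted p under 0.05 in limma). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, read 2.49 in 5-FU on the 2 reversed arrays and 3.66 in cisplatin on 2 of 2 arrays; since CDKN1A helped to set the direction, its sign in 5-FU is no evidence. In cisplatin the p53 targets PLK3 (2.03) and SESN1 (1.92) and the metal-responsive factor MTF1 (1.58) were higher and IRF9 (−1.70) lower. In 5-FU the chromatin genes HMGB2 (−2.09; 3 arrays, −2.64 to −1.54) and H1-10 (−1.86; 3 arrays, −2.67 to −0.35) were lower, and in cytarabine the growth factor EREG (−2.13), the endothelial cadherin CDH5 (−1.58) and the nucleolar gene NOP2 (−1.51). Each is a reading without the channel term.

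SLA, SWT1, C8B, UGT1A10 and ATM belong to a set of falls shared by cytarabine, paclitaxel and cytochalasin D: 376 of 6531 genes fell in all 3 without the channel term (median ratio −0.94), 282 of them also in cisplatin (median −0.65). The channel effect measured on the 5-FU arrays had a median of −0.034 over 177 of these genes (95% bootstrap interval −0.063 to 0.0018). For these 177 the values argue against that measured bias as the whole cause. The rest of the 376 have no channel effect, so the question stays open for them. Over 207 genes the median in 5-FU was −0.061 (−0.129 to −0.028), which argues against an equal response of these genes to all 5 drugs. Both intervals resample genes and do not measure the error between 5-FU arrays. A response that 5-FU shares in part stays open: 55 of the 207 fell in 5-FU without the channel term, against 750 of 5589 genes in all. Faint spots may contribute: 251 of the 376 (66.8%) lack a value on a 5-FU array, against 2741 of 6155 others (44.5%; odds ratio 2.5, Fisher's exact test p = 5.3e-17). A channel bias particular to these arrays, untreated RNA shared between the drugs, and a response that these drugs share all stay open and untested.

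Rises were called whose own arrays lie near 0, such as MAPK6 in cisplatin, UNC5B and MATCAP2 in paclitaxel, and CX3CL1 in cytarabine. Of 655 rises in cytarabine 189 had an array mean under 50% of the fitted ratio, of 540 in cisplatin 220, of 193 in paclitaxel 118 and of 306 in cytochalasin D 181. Noise in a channel effect taken from 1 pair of 5-FU arrays may produce part of them: 350 of 531 rises resting on 1 pair (65.9%) were of this kind against 358 of 1163 resting on 2 pairs (30.8%; odds ratio 4.34). That count pools the drugs, so a gene can enter up to 4 times; within a drug, where each enters once, the odds ratio was 6.91 in cytarabine, 2.03 in cisplatin, 6.99 in paclitaxel and 3.92 in cytochalasin D (Fisher's exact test p = 3.9e-22, 0.000141, 3.7e-09 and 1.1e-07). No biological explanation was tested.

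MDM2, IER3 and the other genes that differed between DNA-directed and cytoskeletal drugs were set against other splits. A limma fit of 2 groups called 0 genes (218 with unadjusted p under 0.05) for the real split of the 10 replicates into 6 and 4, and the highest other of the 100 splits drawn called 30. Since any split calls at least 0, all 100 reach the real count by construction, and these counts decide nothing about chance. This fit has no term for each drug, so the differences between drugs of a class enter its error. With that spread counted, 0 of 3536 genes passed between the classes. The 10 splits of the 5 drugs are too few for a share under 0.05; the real one called 288 genes, the lowest of the 10 (the others 334 or more), and the highest other, cytarabine, paclitaxel and cytochalasin D against 5-FU and cisplatin, called 896. That count, several times the real one, points to a structure of the samples: it sets apart the 3 drugs whose ratios resemble each other, and a response they share was not tested.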

How the results depend on the processing

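The alternatives below were planned, except the differences between the remaining pairs of drugs, chosen after seeing the data. Spot intensities were not analysed here, so the limit that signal sets is unknown; 21.5 to 46.7% of values are missing on the 5-FU arrays.

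MDM2, CCN2, ACTG1 and the other named genes gave 257 results. Over the alternatives run for them (not 1 orientation alone, single probes, robust moderation or a minimum ratio) 3875 values kept direction and side of the threshold, 376 no longer passed (109 of them with only the drugs compared and no channel term), 3 newly passed and 4 changed sign. Part of this agreement was fixed in advance, since the largest rises and falls were named only with the same sign in each replicate. Without the channel term 226 of the 257 stayed the same. Of all calls, 638 of 677 in 5-FU, 832 of 1254 in cytarabine and 501 of 1020 in cisplatin were kept there. In paclitaxel 225 of 476 were kept, and in cytochalasin D 310 of 673. Without the channel term ACTB newly passed in cytarabine (−0.26) and cisplatin (−0.28) and TUBB in paclitaxel (0.28). The changes of sign are AARS1 in cisplatin (−0.10) and MAD2L1 in cytarabine (−0.10), each without the channel term, with all arrays or only those of the drugs compared. Turning the common sign turns the p53 median in 5-FU to −0.24 by construction.

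Without the channel term, where more genes could be tested, 5-FU gave 1127 of 5589 genes and 5-FU against cytarabine 1367 of 5071. With the channel term dropped and only the drugs compared, limma called 0 for 5-FU (1250 unadjusted), 380 for cytochalasin D, 539 for 5-FU against cytarabine and 0 for paclitaxel against cytochalasin D (834 unadjusted); which of these changes decided was not tested. Reversed arrays alone, without the channel term, gave 1180 for 5-FU (447 higher, 733 lower; 517 of its 677 calls kept) and forward arrays alone 996 (440 and 556; 530 kept), a more even balance than 212 and 465. Scaling the arrays gave 819 for cytarabine and 70 for paclitaxel against cytochalasin D, and every array as its own observation gave 8 for the latter; the cause was not tested. A minimum absolute log2 ratio of 1 left 76 genes in 5-FU, 100 in cytarabine, 81 in cisplatin, 53 in paclitaxel, 61 in cytochalasin D, 127 for 5-FU against cytarabine, 4 for paclitaxel against cytochalasin D and 3 for DNA-directed against cytoskeletal drugs, by construction.

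Leaving out 1 replicate gave 578 to 690 genes for 5-FU, 641 to 1219 for cytarabine, 473 to 992 for cisplatin, 151 to 486 for paclitaxel, 207 to 680 for cytochalasin D, 536 to 812 for 5-FU against cytarabine, 7 to 23 for paclitaxel against cytochalasin D and 193 to 350 for DNA-directed against cytoskeletal drugs. A replicate block gave 664, 1261, 940, 479, 640, 799, 20 and 284 in that order. It ended the sterol list in paclitaxel (adjusted p = 0.0638) and 1 call among the 257 results of named genes. Pairing by replicate number gave correlations of −0.0611 to 0.0904. Of 17 list calls, 12 also passed without the channel term; 0 tests passed with an estimated correlation and 51 with fry.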

Other observations

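Genes of the NRF2 and oxidative stress list moved apart in 5-FU. HMOX1 (2.45 ± 0.08), ALDH3A1 (0.81 ± 0.11) and SOD2 (0.53 ± 0.06) rose, while PRDX3 (−1.21 ± 0.06), TXNRD1 (−0.78 ± 0.07), AKR1B10 (−0.47 ± 0.07) and AKR1C1 (−0.30 ± 0.07) fell, out of 13 (median −0.09, mean 0.05 and an upward test, which differ in sign; adjusted p = 0.864). SOD2, AKR1B10 and AKR1C1 were chosen after their values were seen, and AKR1C1 lost its call without 5-FU replicate 1 (−0.25) or 5-FU replicate 2 (−0.36).

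AURKA, chosen for cisplatin after its value was seen, fell in each of the 5 drugs, by −1.67 in 5-FU, −0.82 in cytarabine, −0.41 in cisplatin, −0.68 in paclitaxel and −0.82 in cytochalasin D; in cisplatin its call ended without the channel term (−0.24), without cisplatin replicate 2 (−0.37) and with scaled arrays (−0.30). DUSP6, which dampens ERK signalling, fell in cytarabine (−1.28), cisplatin (−0.72), paclitaxel (−1.17) and cytochalasin D (−1.04), and so did PDK1 (−1.51, −0.78, −0.90 and −0.91). Cytarabine, cisplatin, paclitaxel and cytochalasin D share the channel estimate and the channel of the treated RNA. Their falls in AURKA, DUSP6 and PDK1 are therefore not independent observations, and the causes left open for shared falls apply to them too. Lists of blood and endothelial markers and of fibroblast and muscle markers passed in none of the 5 drugs (adjusted p from 0.803 to 0.912).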
